A study of Mus musculus with 3 samples.

How the data were processed

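The series holds single-cell RNA libraries from mouse skin tumors in which Cre recombinase is driven by the Krt14 promoter, a Rosa26 transgene gives Zeb2 and GFP from a bicistronic transcript, and Trp53 is floxed. The labels give 3 groups of 1 sample each, namely a cultured cell line (CCL), a fully mesenchymal tumor (MSL) and a tumor with a mixed epithelial and mesenchymal phenotype (MIX). Only the MIX tumor was analysed; the counts of the CCL and MSL libraries were not used here. Per the labels' protocols, the tumor was digested with collagenase and dispase, live GFP-positive single cells were sorted by excluding DAPI, and libraries were made on the 10x Genomics platform.

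The deposited matrix holds raw UMI counts per gene and droplet barcode, before any filter on cells. Per the submitters' processing notes, Cell Ranger 4.0.0 and Seurat were used with the genome build GRCm38; the gene annotation and the library kit's chemistry are not given in the sources used here. The deposited counts cover 22554 features, the last of which is GFP, and 6794880 barcodes, of which 853113 had a UMI. Gene positions come from GENCODE M21 on GRCm38, matched by Ensembl identifier for 22513 of the 22554 features. A gene's symbol was used alone where it was unique. Of the features, 52 share their symbol with another identifier, and list members among these were not measured.

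Barcodes were taken as cells with at least 1321.13 UMIs (the 99th percentile of the 3000 barcodes with most UMIs, divided by 10), at least 500 detected genes and at most 20% of UMIs from 13 mitochondrial genes. This left 15713 of 15770 barcodes. Scrublet, run through scanpy with an expected doublet rate of 6%, set its threshold at 0.148 and marked 2735 barcodes (17.4%) as doublets, which were removed. The 12978 kept cells held 46391591 of the 66399346 UMIs (69.9%). Free RNA was described by 43850 barcodes of 20 to 80 UMIs, with 2149769 UMIs in all; this range was chosen after the barcode counts were seen.

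Counts were scaled to 10000 UMIs per cell and log-transformed with scanpy 1.11.5. The 1500 most variable genes of a pool of 11022 were centred, scaled with values limited to 10, and reduced to 30 principal components. Cells were joined to 15 neighbours and clustered with the Leiden method of igraph 0.11.9 at resolution 0.5. The pool held the cell type markers and a seeded random draw of the other genes, without the reported gene lists, so that the values of the lists had no part in making the clusters. Lists of genes that vary together with the markers can still differ between the named classes for that reason. Clusters were named from 15 marker lists fixed before the data were examined (epithelial, mesenchymal, T or NK cell, B cell, macrophage or monocyte, dendritic or Langerhans cell, neutrophil, mast cell, endothelial, pericyte or smooth muscle, melanocyte, Schwann cell, skeletal muscle, adipocyte and erythroid). A cluster took the name of the list with most markers at least 2-fold above the rest of the cells, with at least 20 UMIs and 20 CPM, if there were 3 or more; this scoring rule was set after the clusters were seen. Clusters that met it for no list stayed unnamed.

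With 1 library per group there is no replicate, and cells are not replicates, so no test was run. UMIs were summed over the cells of a class or cluster and scaled to the class or cluster total as CPM. Class shares have exact Clopper-Pearson 95% intervals, and ratios of 2 classes have exact conditional binomial 95% intervals; all of them cover counting error only. For ranks, list medians and the alternatives, a class with under 3 UMIs of a gene entered the ratio at a floor of 3 UMIs; a ratio printed for 1 or 2 UMIs is that of the counts as they were unless said otherwise, and one for 0 UMIs is a bound at the floor. For a gene list, the median log2 ratio was taken over the members with at least 50 UMIs in both classes together and placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Random lists were drawn gene by gene, so a percentile does not allow for members that vary together or with the markers. Intervals of list medians come from 1000 Poisson draws of the counts.

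The rule for named genes and 29 reported lists were fixed before the data were examined. Named were Zeb2, Zeb1, Trp53, Krt14 and GFP; the 12 genes with the highest and the 12 with the lowest ratio, among genes with at least 200 UMIs in both classes together that were outside the clustering pool (4238 genes); and up to 2 members with the highest and 2 with the lowest ratio of each list. Some genes that this rule names are not reported here. Cells with both marker sets were counted after thinning each cell to 1763 UMIs, the 10th percentile of the kept cells, which left out 1297 cells (295 epithelial-like, 827 mesenchymal-like, 104 unnamed and 71 of other types). For comparison, 4000 doublets were simulated by adding the UMIs of random pairs of cells.

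The ratio step was tested on simulated counts for the mesenchymal-like against epithelial-like comparison, with 7944 genes of which 200 were changed. Intervals held the true fold for 96% of the genes changed 1.5-fold, 100% of those changed 2-fold, 94% of those changed 4-fold, 98% of those changed 8-fold, and 95.3% of 7744 unchanged genes. A scan along the chromosomes took the median log2 ratio in windows of 10 neighbouring genes. A stretch was grown from the highest window while enough of the next genes were at least 4-fold higher, and was trimmed to end on such genes. On simulated counts of clusters 4 and 2, with 10020 genes and a block raised by 2 on the log2 scale, the highest window had a median of 2.01 and held 9 of its 10 genes inside the block; in clusters 7 and 0, with 4349 genes, it had 2.27 and held 10.

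Alternatives covered the UMI minimum, the mitochondrial limit, doublet removal, the clustering resolution, the number of components, the clustering genes, the weighting of cells, subtraction of free RNA, the UMI minimum for list members and the UMIs asked of each marker set. With a fixed minimum of 1000 UMIs, a doubled minimum and a mitochondrial limit of 10%, Scrublet's automatic threshold marked 0 cells, so the threshold of the main run was applied to its scores there. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.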

Results

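The MIX tumor library measured RNA in 12978 single cells sorted for GFP from a skin tumor of mixed epithelial and mesenchymal phenotype. Its 66399346 UMIs gave each kept cell between 1322 and 17429 UMIs, with a median of 3235 UMIs and 1460 genes, and 16753 features had at least 1 UMI. There was 1 sample and no replicate, so every interval covers counting error only. The design asks how epithelial and mesenchymal states, and cells between them, make up such a tumor.

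Clustering gave 9 groups of cells. Epithelial-like cells, led by keratin and desmosome genes, were clusters 2 (2705 cells) and 4 (166 cells) and made up 22.1% of the cells (95% interval 21.4 to 22.8). Mesenchymal-like cells, in clusters 1 (3944 cells) and 8 (39 cells), made up 30.7% (29.9 to 31.5). Clusters 0 (4727 cells) and 3 (1204 cells) met the naming rule for no list and held 45.7% of the cells (44.8 to 46.6). Cells of other types, in endothelial-like cluster 5 (76 cells), macrophage-like cluster 6 (63 cells) and cluster 7 (54 cells), made up 1.49% (1.29 to 1.71). Cluster 7 met the naming rule for macrophages through Cd68, Csf1r, Tyrobp and Fcer1g, but Ctsk, Acp5 and Mmp9, genes of osteoclasts, led it and Adgre1 had 0 UMIs, so it is called by its number. The mesenchymal-like share depended on the processing: it was 22.2% with a doubled UMI minimum and 40.0% with a mitochondrial limit of 10%. Mesenchymal-like cells had a median of 2217 UMIs, epithelial-like cells 2801 and the unnamed clusters 4405, so a UMI minimum acts on these shares unequally.

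The remaining marker lists named no cluster. Over all kept cells, their members held 573 UMIs for T or NK cells, 17 for B cells, 2054 for dendritic or Langerhans cells, 1166 for neutrophils and 0 for mast cells. Pericyte or smooth muscle markers held 960 UMIs, melanocyte markers 269, Schwann cell markers 81, skeletal muscle markers 66, adipocyte markers 398 and erythroid markers 366. Epithelial markers held 113074 UMIs, mesenchymal markers 585079, macrophage or monocyte markers 3033 and endothelial markers 963.

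**Figure D1:**
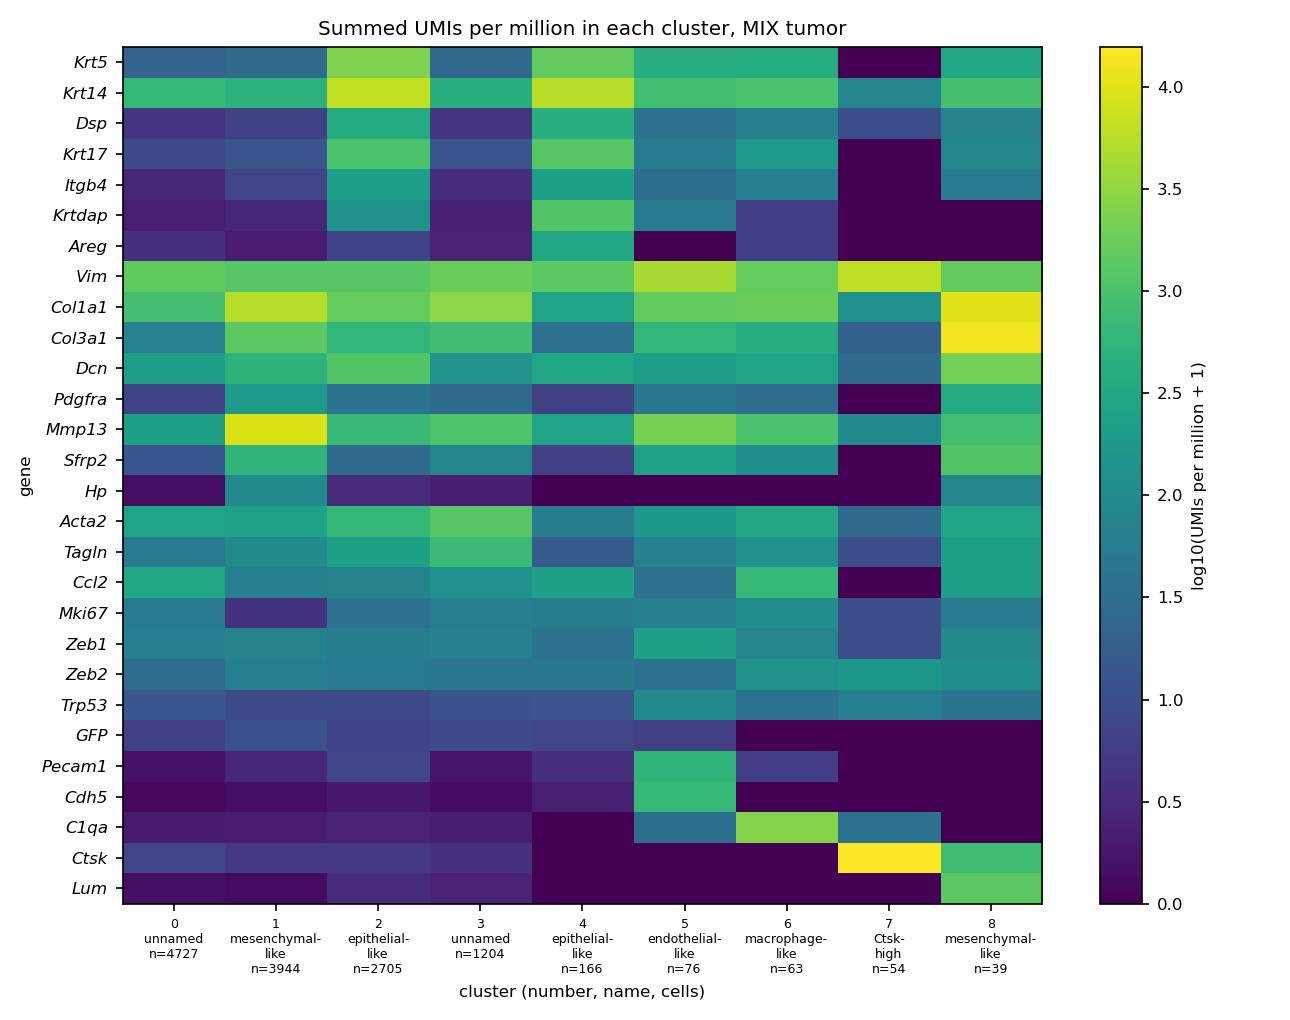
Level of 28 genes (rows) in the 9 clusters (columns, with their number of cells), as log10 of CPM plus 1. Krt5 and Dsp are high in clusters 2 and 4, Mmp13 reaches 9464 CPM in cluster 1, and Acta2 reaches 1270 CPM in cluster 3.

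Zeb2, Zeb1 and GFP had ratios of mesenchymal-like over epithelial-like cells from 1.22 to 1.62. Zeb2 (ENSMUSG00000026872, chromosome 2, 44983632 to 45117395), a repressor of epithelial genes, was at 63.6 CPM in mesenchymal-like and 52.0 CPM in epithelial-like cells, a ratio of 1.22 (1.08 to 1.38). Its relative Zeb1 had a ratio of 1.27 (1.13 to 1.43) and GFP one of 1.62 (1.15 to 2.31). Subtracting free RNA at the largest share that the markers of the opposite class allow, a loose 46.0% of epithelial-like UMIs set by Pdgfrb, gave 0.843 for Zeb2 and 0.872 for Zeb1. With the shares that all abundant genes of free RNA allow at their upper counting limit, 13.2% of epithelial-like UMIs set by Klra4 and 4.74% of mesenchymal-like UMIs set by Krt5, the ratio of Zeb2 was 1.16 and the ratio of Zeb1 1.204; this alternative was chosen after the data were seen. By cluster, Zeb2 was lowest in cluster 0, at 30.2 CPM, and reached 174 CPM in cluster 7. GFP was at 5.27 CPM in cluster 0 and 9.87 CPM in cluster 1, with 0 UMIs in clusters 6, 7 and 8. The sources used here do not give whether tags of the bicistronic transcript were counted as Zeb2, as GFP or as neither, so both values may miss the transgene in part or whole.

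Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), the floxed tumor suppressor, was at 8.52 CPM in mesenchymal-like and 7.73 CPM in epithelial-like cells, a ratio of 1.10 (0.789 to 1.54). It was at 99.6 CPM (59.96 to 156), from 19 UMIs, in endothelial-like cluster 5. Clusters 6, 7 and 8 had 35.6 CPM (14.3 to 73.3), 64.1 CPM (25.8 to 132) and 41.7 CPM (11.4 to 107), from 7, 7 and 4 UMIs. Among clusters 0 to 4, Trp53 ran from 7.34 CPM in cluster 2 to 12.7 CPM in cluster 0. Tags outside the deleted part do not report on the deletion.

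Genes of epithelial identity were far lower in mesenchymal-like than in epithelial-like cells. The intervals of single genes cover counting error only: of 131 ratios of named genes, 65 moved by over 1.5 times in at least 1 alternative other than the subtraction of free RNA, 58 of them toward 1, with 45 moved by a doubled UMI minimum and 36 by keeping doublets. Of 10 measured hemidesmosome and basement membrane adhesion genes, which anchor basal keratinocytes, 7 were at least 2-fold lower, and the list's median log2 ratio was -3.36 (-3.62 to -3.15). Itga6 was 83.5-fold (53.8 to 137) and Col17a1 70.7-fold (44.5 to 120) higher in epithelial-like cells, while Dst was 1.31-fold higher there and Col7a1, an anchoring fibril collagen, was 1.46-fold (1.32 to 1.61) higher in mesenchymal-like cells. Of 17 epidermal differentiation genes, 7 had at least 50 UMIs in both classes together, with a median of -4.25 and 6 of 7 at least 2-fold lower. Krtdap was 109-fold (70.2 to 178) higher in epithelial-like cells, Sbsn 4.71-fold, and Krt10 close to equal at 1.16 (0.902 to 1.49) over epithelial-like cells. Stress keratins and wound-edge genes had the lowest median, -5.51, with Krt6a 98.6-fold (74.8 to 133) and Krt17 79.5-fold (66.6 to 95.6) higher in epithelial-like cells. Slpi was only 1.27-fold higher there, and Lcn2, with 3 epithelial-like UMIs, had a ratio of 15.5 (5.02 to 77.8) towards mesenchymal-like cells, which was 2.76 with a doubled UMI minimum. Krt6a and Krt17 have close paralogs, and reads shared with these could move between them.

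Of 20 junction and polarity genes, 9 had at least 50 UMIs in both classes together, with a median of -3.97 and 7 of 9 at least 2-fold lower. Spint2 was 72.7-fold (35.0 to 182) and Dsg3, with 2 mesenchymal-like UMIs, 139-fold (38.1 to 1154) higher in epithelial-like cells, whereas Cgn and Pkp2 had ratios of 1.40 (0.933 to 2.13) and 1.24 (0.955 to 1.61). Of 14 epithelial transcription and splicing regulators, 6 had enough UMIs, with a median of -3.42 and 5 of 6 at least 2-fold lower. Tfap2c was 18.9-fold and Ehf 3.74-fold higher in epithelial-like cells, and Tfap2a had a ratio of 1.24. Hair follicle and adnexal genes were split, with a median of -0.33. Lgr5, a follicle stem cell gene, was 6.37-fold (4.88 to 8.43) and Lrig1 3.12-fold higher in mesenchymal-like cells, and Nfatc1 was 12.8-fold (7.26 to 24.6) and Cd34 5.47-fold higher in epithelial-like cells; the ratio of Cd34, mesenchymal-like over epithelial-like cells, was 0.623 with a mitochondrial limit of 10%. Of the simple-epithelium genes, 2 had enough UMIs: Krt7 was 3.58-fold higher in mesenchymal-like cells and Anxa8 3.33-fold higher in epithelial-like cells, giving a median of 0.05.

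**Figure D2:**
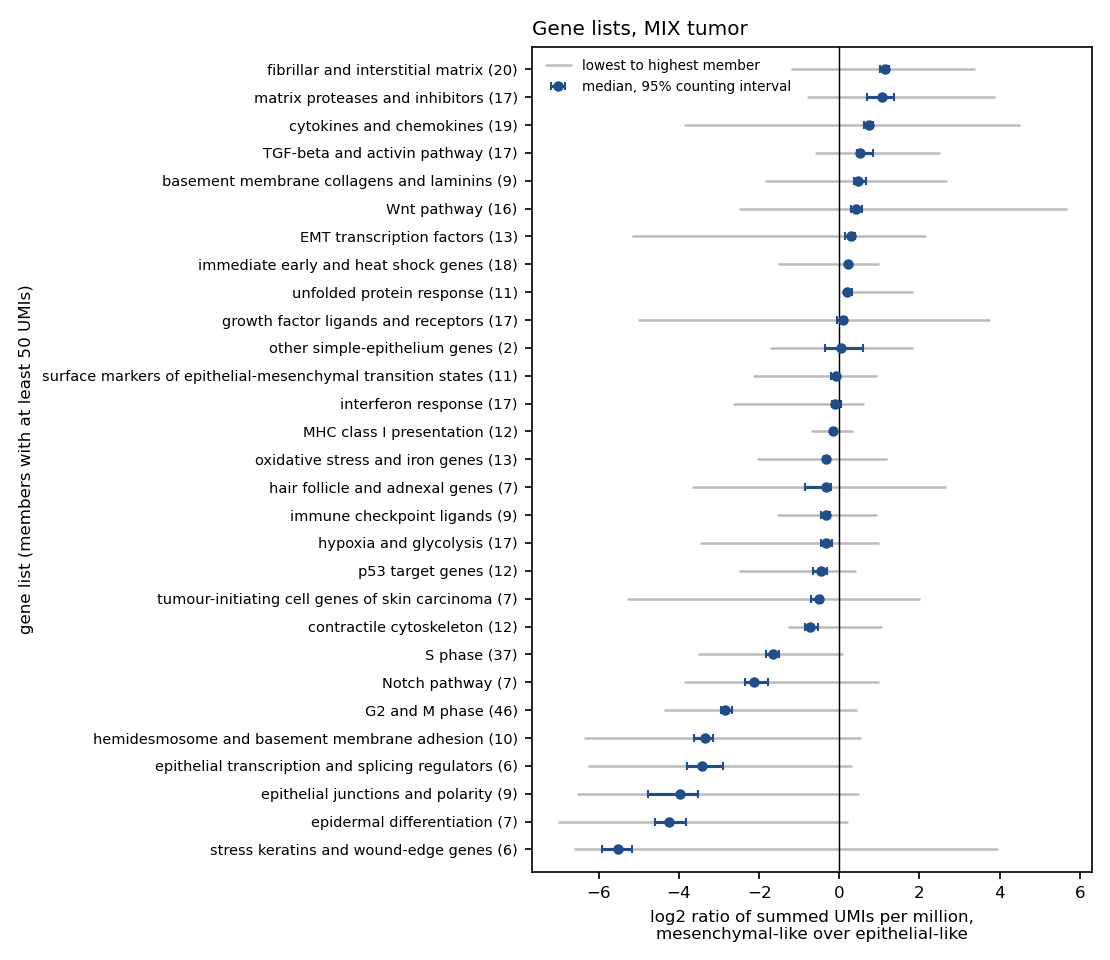
Median log2 ratio of CPM, mesenchymal-like over epithelial-like cells, for each of 29 gene lists (points, with 95% counting intervals), and the span from the lowest to the highest member (grey lines). The medians run from -5.51 for stress keratins to 1.14 for fibrillar and interstitial matrix.

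Extracellular matrix and its remodelling enzymes were higher in mesenchymal-like cells. The markers that named these cells include Col1a1, Col1a2, Col3a1 and Fn1. The direction for matrix genes, and their percentile among random lists, are therefore not independent of the naming. Fibrillar and interstitial matrix genes had a median of 1.14 (1.01 to 1.24), above all 10000 random lists (percentile 100), with 11 of 20 at least 2-fold higher and 1, Fbln1, at least 2-fold lower. The collagen cross-linking enzymes Lox and Loxl1 were 10.5-fold (9.49 to 11.6) and 5.11-fold (4.57 to 5.72) higher, and Bgn had a ratio of 0.987, which was 0.300 without the 39 cells of cluster 8. Proteases and their inhibitors had a median of 1.07, with 9 of 17 at least 2-fold higher and 0 at least 2-fold lower. Mmp13, a collagenase, was 14.6-fold (14.2 to 14.9) and Mmp3 14.8-fold (14.1 to 15.5) higher, and Adam12 was 1.75-fold and Plaur 1.32-fold higher in epithelial-like cells. With a doubled UMI minimum the ratio of Mmp13 was 7.69, and with doublets kept the ratio of Mmp3 was 7.49 and the ratio of Lox 5.77. With free RNA subtracted at 13.2% of epithelial-like UMIs they were 21.9, 28.7 and 15.3, and at 46.0% it left no epithelial-like UMIs of these genes. Mmp13 and Mmp3 lie in a stretch of chromosome 9 that is described below, but their levels did not follow its gene Yap1. In clusters 0 to 4, in order, Mmp13 was at 238, 9464, 679, 1100 and 277 CPM. Mmp3 was at 91.5, 3274, 195, 413 and 485 CPM, and Yap1 at 1426, 1629, 1146, 2154 and 1453 CPM. Basement membrane collagens and laminins had a median of 0.47 (percentile 98.7), with Col4a1 6.396-fold and Col4a2 3.60-fold higher in mesenchymal-like cells and Lama5 3.64-fold and Col18a1 1.24-fold higher in epithelial-like cells; Col4a1 was at 3.05 with a doubled UMI minimum.

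Transcription factors of epithelial-mesenchymal transition (EMT) had a small median difference, 0.29, at the 94.3rd percentile of random lists. With free RNA subtracted, this median turned to -0.25 at the loose share from markers and stayed above 0 at the share that all abundant genes allow. Prrx2 was 4.50-fold (3.88 to 5.23) and Twist1 4.04-fold (2.83 to 5.91) higher in mesenchymal-like cells, while Sox11 was 36.4-fold (25.01 to 55.1) and Foxc2 1.59-fold higher in epithelial-like cells. With a doubled UMI minimum the ratio of Sox11, mesenchymal-like over epithelial-like cells, rose from 0.0275 to 0.131. The surface markers used to sort EMT states had a median of -0.08. Ly6a was 4.48-fold (4.26 to 4.70) and Cd44 2.26-fold higher in epithelial-like cells, and Itgb3 1.90-fold and Itga5 1.22-fold higher in mesenchymal-like cells. Contractile genes had a median of -0.74, with Tagln2 2.43-fold and Acta2 2.26-fold (2.15 to 2.37) higher in epithelial-like cells and Cnn2 2.08-fold and Tpm1 1.47-fold higher in mesenchymal-like cells. This median turned positive, up to 0.34, where a further cluster rich in Acta2 was named mesenchymal-like. The ratio of Acta2, mesenchymal-like over epithelial-like cells, also rose above 1 there, up to 1.29.

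Signalling genes differed by pathway. The TGF-beta and activin list had a median of 0.52 (percentile 99.9), with 7 of 17 at least 2-fold higher. Ccn2 was 5.69-fold (5.29 to 6.13) and Ltbp2 4.31-fold higher in mesenchymal-like cells, and Tgfb1 was 1.52-fold and Tgfbr2 1.16-fold higher in epithelial-like cells. Wnt pathway genes had a median of 0.42 (percentile 99.1). The secreted Wnt modulators Dkk2 and Sfrp2 were 50.9-fold (24.5 to 127) and 22.2-fold (19.4 to 25.5) higher in mesenchymal-like cells, and Sfrp1 was 5.63-fold and Wnt7b 2.10-fold higher in epithelial-like cells. With doublets kept, Dkk2 was at 9.77, and with a doubled UMI minimum Sfrp2 was at 9.13; without cluster 8 the ratio of Sfrp1 was 0.0886. Notch pathway genes had a median of -2.12, which was -0.80 when members with at least 10 UMIs entered the list, with Jag2 14.6-fold (10.3 to 21.2) and Jag1 5.65-fold higher in epithelial-like cells and Notch2 1.99-fold and Hes1 1.28-fold higher in mesenchymal-like cells. Growth factors and receptors were split around a median of 0.08. Igf1 was 13.6-fold (7.61 to 26.9) and Fgf7 8.19-fold higher in mesenchymal-like cells, and without cluster 8 the Igf1 ratio was 5.54. With a doubled UMI minimum Igf1 was at 4.55, and with doublets kept Fgf7 was at 3.89. The EGF receptor ligand Areg was 32.7-fold (17.5 to 68.9) higher in epithelial-like cells, and Tgfa, with 0 mesenchymal-like UMIs, at least 27.0-fold. Cluster 4 held most of the Areg UMIs, and without it the ratio of mesenchymal-like over epithelial-like cells was 0.170 for Areg.

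Cell cycle genes were lower in mesenchymal-like cells, which were mostly those of cluster 1, than in epithelial-like cells. Of 46 G2 and M phase genes, 39 were at least 2-fold lower, with a median of -2.85 (-2.95 to -2.67), and of 37 S phase genes, 30 were, with a median of -1.66. The G2 and M phase median was -1.13 with a mitochondrial limit of 10%, where a further cluster was named mesenchymal-like. Aurkb was 20.6-fold (8.51 to 64.8), Hmmr 18.5-fold, E2f8 11.5-fold and Rrm2 10.6-fold higher in epithelial-like cells, while Cbx5, at 1.35, Hjurp, at 1.24 towards epithelial-like cells, Gins2, at 1.07, and Casp8ap2, at 1.12 towards epithelial-like cells, were within 2-fold. Over all alternatives the ratio of Gins2 ran from 0.960 to 41.0. With the mitochondrial limit of 10% the ratios of mesenchymal-like over epithelial-like cells were nearer to 1, at 0.292 for Aurkb, 0.296 for Hmmr and 0.275 for Rrm2, and with a minimum of 1000 UMIs E2f8 was at 0.217. Targets of p53 had a median of -0.46. The cell cycle inhibitor Cdkn1a was 4.10-fold (3.42 to 4.93) and Gtse1 5.69-fold higher in epithelial-like cells, and Bbc3 and Zmat3 had ratios of 1.34 and 1.06.

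Cytokine and chemokine genes had a median of 0.73 (percentile 99.99), with 8 of 19 at least 2-fold higher and 3 lower. Tnfsf11, the osteoclast differentiation factor RANKL, was 22.9-fold (14.5 to 38.4) and Tslp 19.0-fold (7.13 to 71.2) higher in mesenchymal-like cells, and Cxcl14 was 14.7-fold (12.8 to 16.9) and Ccl7 2.95-fold higher in epithelial-like cells. Tnfsf11 was at 10.4 with a doubled UMI minimum, Tslp at 7.72 with doublets kept and Cxcl14 at 0.0322 without cluster 8. Interferon response genes had a median of -0.10 (percentile 32.5), MHC class I genes one of -0.16 (19.0) and checkpoint ligands one of -0.33 (10.8), with 1 of 17, 0 of 12 and 1 of 9 members at least 2-fold lower and 0 higher. In these lists, Bst2 (1.53), Ifit1 (1.32), Tapbp (1.26), H2-T23 (1.21), Nectin2 (1.92) and Lgals3 (1.23) were the members highest in mesenchymal-like cells. Under alternatives, Ifit1, H2-T23 and Lgals3 fell below a ratio of 1, down to 0.814, 0.998 and 0.802. Ifi27l2a was 6.33-fold (5.67 to 7.08), Nlrc5 1.62-fold, Erap1 1.53-fold, Cd276 2.92-fold and Cd200 1.91-fold higher in epithelial-like cells.

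Hypoxia and glycolysis genes had a median of -0.34, with Egln3 11.1-fold (7.58 to 16.7) and Pfkp 3.74-fold higher in epithelial-like cells and P4ha2 2.00-fold and Ndrg1 1.66-fold higher in mesenchymal-like cells. The oxidative stress and iron list had a median of -0.33, with Slc7a11, the cystine transporter, 4.18-fold and Tfrc 2.51-fold higher in epithelial-like cells and Hmox1 2.30-fold and Fth1 1.41-fold higher in mesenchymal-like cells. Genes of tumor-initiating cells had a median of -0.51. Pitx1, with 1 mesenchymal-like UMI, was 118-fold (20.8 to 4712) and Aldh3a1 7.97-fold higher in epithelial-like cells, and Bmi1 was 1.12-fold higher there; without cluster 4 the ratio of Pitx1, mesenchymal-like over epithelial-like cells, was 0.0808. Immediate early and heat shock genes had a median of 0.23, with Dusp1 1.98-fold and Nr4a1 1.96-fold higher in mesenchymal-like cells and Atf3 2.90-fold and Hspa1b 2.61-fold higher in epithelial-like cells. The unfolded protein response had a median of 0.20, with Chac1 3.56-fold and Trib3 3.32-fold higher in mesenchymal-like cells and Sdf2l1 and Dnajb9 each at a ratio of 1.04.

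Outside the clustering genes, the highest ratio was that of Osr2. This transcription factor, with 2 epithelial-like UMIs, was 106-fold (28.9 to 877) higher in mesenchymal-like cells, at 24.0 CPM (ENSMUSG00000022330, chromosome 15, 35296098 to 35303305). Genes were ranked with a class of under 3 UMIs taken at 3, which put Osr2 at 70.4-fold. After it came Dkk2, Hp (49.2-fold, 31.0 to 83.4), Ptgfr (48.0-fold), Rftn1 (30.9-fold), Sept4 (28.5-fold), Ndnf (27.9-fold), Tnfsf11, Sfrp2, Klhl33 (21.7-fold), Rgs17 (20.6-fold) and Olfml2b (19.3-fold). These ratios depended on the processing: with a doubled UMI minimum Osr2 was at 7.65, Hp at 5.08 and Ptgfr at 10.9, with doublets kept Rgs17 was at 2.27, and the lowest values over all alternatives ran from 2.27 for Rgs17 to 10.9 for Ndnf. At the other end, Aqp3, a water and glycerol channel, was 143-fold (60.8 to 440) higher in epithelial-like cells (chromosome 4, 41092722 to 41098183), and Dmkn, with 3 mesenchymal-like UMIs, 130-fold (44.2 to 635). Krtdap, Krt6a, Plek2 (96.6-fold), Krt42 (92.8-fold), Dsg3 (92.7-fold with its 2 mesenchymal-like UMIs taken at 3), Itga6, Krt17, Lad1 (76.1-fold) and Spint2 followed in this ranking. Over all alternatives, the highest ratios of mesenchymal-like over epithelial-like cells of these 11 genes ran from 0.0114 for Aqp3 to 0.0314 for Lad1. Krt14, which also served as a marker, was 12.2-fold (11.9 to 12.6) higher in epithelial-like cells.

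**Figure D3:**
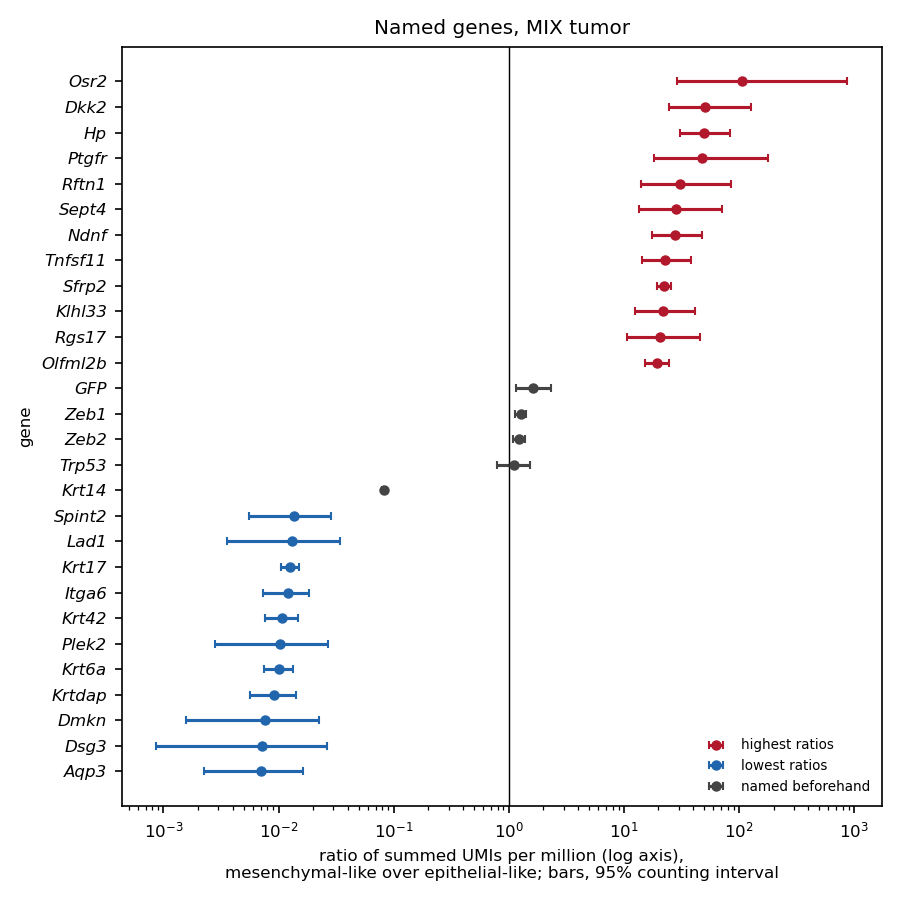
Ratio of CPM, mesenchymal-like over epithelial-like cells, on a log axis, for the 12 highest, 11 of the 12 lowest and the 5 genes named beforehand; bars are 95% counting intervals. Zeb1, Zeb2, GFP and Trp53 lie between 1.10 and 1.62.

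Compared by cluster number, the unnamed clusters were neither keratin-rich nor as rich in matrix as cluster 1. Krt5 was at 19.5 CPM in cluster 0 and 25.1 CPM in cluster 3, against 2396 CPM in cluster 2, and Col1a1 was at 923 and 2947 CPM, against 5448 CPM in cluster 1. In cluster 0 the G2 and M phase list had a median log2 ratio of 1.00 over the other clusters pooled, with 25 of 47 genes at least 2-fold higher. The median was -3.35 in cluster 1, -0.20 in cluster 2, 0.25 in cluster 3 and 0.49 in cluster 4. Each cluster was set against its own pool, so these medians do not rank the clusters. Summed over the list, the level was 3311 CPM in cluster 0, 675 in cluster 1, 2047 in cluster 2, 2940 in cluster 3 and 3404 in cluster 4. The Wnt genes of cluster 0 had a median of -2.36 and its fibrillar matrix genes one of -1.28. The chemokine Ccl2 was at 314 CPM in cluster 0, 3.50-fold (3.33 to 3.67) above the other clusters among 0 to 4. It was higher, at 645 CPM, in macrophage-like cluster 6. Cluster 3 was led by contractile genes, with Tagln at 713 CPM, 7.04-fold (6.74 to 7.36), and Acta2 at 1270 CPM, 3.80-fold (3.69 to 3.91) above the other clusters; with 4 of 13 at least 2-fold higher, its contractile list had a median of 0.49.

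The small epithelial-like cluster 4 differed from cluster 2. Hypoxia and glycolysis genes had a median of 1.46 over the other clusters there, with 11 of 17 at least 2-fold higher. Summed over the list, their level was 3791 CPM in cluster 4 and 2278 CPM in cluster 2. MHC class I genes had a median of -1.23, with 9 of 12 at least 2-fold lower, and interferon response genes one of -1.12, with 12 of 17 at least 2-fold lower. Fibrillar matrix genes had a median of -2.15 over the other clusters in cluster 4. Their summed level was 1397 CPM there and 4790 CPM in cluster 2. Areg was at 331 CPM in cluster 4, 118-fold (94.5 to 147) above the other clusters, Krtdap at 1117 CPM and Krt6a at 1594 CPM. A stretch of neighbouring genes on chromosome 6 was also raised together in cluster 4.

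Cells with both marker sets were counted at a depth of 1763 UMIs. At least 3 UMIs of epithelial and 3 of mesenchymal markers were found in 30.8% (29.96 to 31.6) of 11681 cells, namely in 93.9% (92.9 to 94.8) of epithelial-like, 11.5% (10.4 to 12.6) of mesenchymal-like and 13.6% (12.8 to 14.6) of unnamed cells. In clusters 5, 6 and 7, whose cells should lack keratins, the share was 17.2% (10.98 to 25.1). By the abundant free RNA gene least present in each cluster, free RNA made up at most 24.1% of the UMIs in cluster 5, 20.3% in cluster 6 and 4.74% in cluster 7, against 2.74% in cluster 0, 4.31% in cluster 1 and 3.70% in cluster 3. At the upper limit of the share that Krt5 allows in mesenchymal-like cells, 4.74%, free RNA would give 3 epithelial marker UMIs in 0.281% of them. In epithelial-like cells, it would give 3 mesenchymal marker UMIs in 98.6% of cells at the 46.0% that Pdgfrb allows and in 39.997% at the 13.2% that Klra4 allows, against the 97.6% that held them. The median depths before thinning were 2801 UMIs in epithelial-like cells and 2070 in cells of other types. Simulated doublets gave 43.1% (41.6 to 44.7). Without thinning the overall share was 50.5%. Vim, S100a4 and Sparc are expressed by many cell types; without them the share was 24.45% (23.7 to 25.2) of all cells and 68.8% (66.9 to 70.5) of epithelial-like cells.

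The collagen genes carried much of this overlap in cluster 2. Of its cells, 61.9% (59.9 to 63.8) had at least 3 UMIs of Col1a1 and Col1a2, and 56.6% (54.6 to 58.6) had these together with at least 3 of Krt5 and Krt14, against 7.93% (4.29 to 13.2) of cluster 4. In the other direction, Krt14 was at 643 CPM in cluster 0 and 511 CPM in cluster 1, below the 2238 CPM of free RNA. Its ratio to Krt5, however, was 32.9 (29.9 to 36.3) in cluster 0, 18.8 (16.6 to 21.4) in cluster 1 and 16.7 (14.04 to 19.97) in cluster 3, against 3.14 (2.96 to 3.33) in free RNA and 2.65 (2.61 to 2.70) in cluster 2, and free RNA keeps its genes in 1 ratio.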

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

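Cells of types that a sort for GFP in Krt14-driven tumor cells would not be looked to hold were present, a signal outside the comparison of tumor cells. Endothelial-like cluster 5, macrophage-like cluster 6 and cluster 7 held 193 of the 12978 kept cells, 1.49% (95% interval 1.29 to 1.71). GFP gave 1 UMI in endothelial-like cluster 5 and 0 in clusters 6 and 7. At 1763 UMIs per cell, GFP was found in 1.56% (1.16 to 2.06) of cells of cluster 1 and 1.24% (0.841 to 1.77) of cells of cluster 2, and in 0 of 40 cells of cluster 6 (up to 8.81%), so its absence from the small clusters was not detectable at this depth. No explanation was tested.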

How the results depend on the processing

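The removal of the highest 6% of doublet scores and the alternatives without cluster 4, without cluster 8, without Vim, S100a4 and Sparc and with free RNA subtracted at the share that all its abundant genes allow were chosen only after the results were seen. Mesenchymal-like cells were 35.3% with a minimum of 1000 UMIs, 22.2% with the doubled minimum, where the number of cells kept was 8366, 40.0% with a mitochondrial limit of 10%, 24.9% with doublets kept, 27.2% with the highest 6% of doublet scores removed, 28.7% at resolution 1.0, 28.2% with all genes in the clustering pool and 34.7% with another random draw of clustering genes. Epithelial-like cells were 20.4% with the doubled minimum, 23.1% with the mitochondrial limit of 10%, 26.1% with doublets kept and 23.7% with the highest 6% removed. Cells of other types were 1.80% with 1000 UMIs, 1.88% with doublets kept and 1.92% with the highest 6% removed. Cells with both marker sets were 28.8% with 1000 UMIs, 32.6% with the doubled minimum, 32.2% with the mitochondrial limit, 34.4% with doublets kept, 32.1% with the highest 6% removed, 45.0% and 20.7% with at least 2 and 5 UMIs of each set, 50.5% with all UMIs and 24.45% without Vim, S100a4 and Sparc. With 1000 UMIs, the doubled minimum and the mitochondrial limit of 10%, a further cluster, of 1652, 721 and 1456 cells, was named mesenchymal-like. Beyond this, the cause was not tested for these shares.

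The medians of the hemidesmosome, differentiation, junction, stress keratin, S phase and G2 and M phase lists stayed below 0 and those of the fibrillar matrix, protease, TGF-beta, Wnt and cytokine lists above 0 in every alternative run, from 0.89 to 1.25 for fibrillar matrix and from -3.37 to -1.13 for G2 and M phase. The contractile list turned positive with 1000 UMIs (0.17), the doubled minimum (0.34), the mitochondrial limit of 10% (0.22) and another random draw of clustering genes (0.11), as did the Acta2 ratio (1.06, 1.29, 1.07 and 1.02); in these settings a cluster rich in Acta2 was named mesenchymal-like. The surface marker list turned to 0.022 with 1000 UMIs and 0.026 with another random draw of clustering genes. Also reversed was a further list median: immediate early and heat shock genes gave -0.074 with the doubled minimum, -0.0455 with the mitochondrial limit and -0.25 with free RNA subtracted. Subtraction of free RNA, at a bound of 46.0% for epithelial-like cells that Pdgfrb leaves loose, also turned the EMT factor list (-0.25), Zeb2 (0.843), Zeb1 (0.872), the ratio of Tfap2a (0.958) and the ratio of Hes1 (0.953). At the shares that all abundant genes of free RNA allow, 13.2% for epithelial-like cells, and 4.74% for mesenchymal-like cells, where Krt5 sets both shares and the first, 4.23%, leaves out its counting error, no called value reversed: the list median: EMT transcription factors was 0.21, the ratio of Zeb2 1.16 and the ratio of Zeb1 1.204. The Notch list ran from -2.85 with free RNA subtracted at the shares from markers to -0.80 with members of at least 10 UMIs. With members of at least 200 UMIs, 3 genes of the hair follicle list remained and gave 1.64.

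Further ratios of single genes that crossed 1, among those whose interval excluded 1, were the ratio of Lgals3 (0.999 with 1000 UMIs, 0.802 with the doubled minimum, 0.926 with the mitochondrial limit), Tgfbr2 (1.02, doubled minimum), Hes1 (0.826, doubled minimum, and 0.940, mitochondrial limit), Tfap2a (0.955) and H2-T23 (0.998) with the mitochondrial limit, Ifit1 (0.814) with all genes in the pool and Plaur (1.02) without cluster 4. Bgn, Zmat3, Sdf2l1, Dnajb9, Gins2 and Bmi1, whose intervals held 1, also crossed it. Apart from the cases tied to an added cluster or to fewer members, the cause was not tested. Medians whose intervals held 0 also changed sign, from -0.28 to 0.36 for growth factors, from -1.73 to 0.33 for simple-epithelium genes and from -0.42 to 0.23 for interferon response genes. Of the ratios of named genes under the alternatives, 1449 stayed within their counting interval, 498 left it without a called reversal and 18 reversed. With free RNA subtracted at the shares from all abundant genes, 29 of the 131 ratios moved by over 1.5 times, 0 of them toward 1, and at the shares from markers 76, 2 of them toward 1. The 39 cells of cluster 8 and the low counts of Trp53 and GFP limit what depth can show.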

Other observations

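The tests below on UMIs per droplet, on how many cells of cluster 4 carried the chromosome 6 signal and on cluster 5 against cluster 2 were set before their results were seen; all other tests of this part, and the genes named in it, were chosen only after the result was seen.

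At resolution 1.0 most epithelial-like cells fell into clusters of 1928 and 787 cells, the second holding 774 cells of cluster 2. In the smaller, Sfrp1 was 37.7-fold (25.8 to 57.0), Aspn 22.6-fold, Col6a3 13.1-fold, Bgn 11.7-fold and Prrx1, an EMT factor, 10.3-fold (7.73 to 14.04) higher, and Zeb2 was 1.88-fold (1.54 to 2.30) higher. In the larger, 3 of 5 stress keratin and wound-edge genes and 4 of 7 epidermal differentiation genes were at least 2-fold higher, with Krtdap 34.3-fold (19.1 to 69.0), Gjb2 17.2-fold, Dsg3 16.1-fold, Sox11 9.90-fold and Krt17 6.36-fold higher. Itgb4 was at a ratio of 0.950 (0.850 to 1.06), smaller over larger. Of the G2 and M phase genes, 28 of 44 were at least 2-fold lower in the smaller cluster, with a median of -1.20, and of the S phase genes 24 of 33. With 9 of 20 at least 2-fold higher and 1 lower, fibrillar matrix genes had a median of 0.53, while 2 of 16 proteases and inhibitors were at least 2-fold higher and 1 lower (median 0.31), and of 8 basement membrane genes 0 were higher and 1 lower (0.050).

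Cluster 2 held Col1a1 at 1608 CPM and Col1a2 at 2154 CPM beside its keratins, with more in the smaller of its groups at resolution 1.0 (Col1a1 2873 against 1211 CPM, Dcn 4247 against 101 CPM), and cells with at least 3 collagen UMIs had a lower share of the chromosome 9 stretch described below than cells with none (medians 0.416% and 0.912%). The abundant genes of free RNA allow it at most 10.5% of the UMIs of cluster 2, a share set by Klra4. Over Col1a1, Col1a2, Col3a1, Fn1, Dcn and Sparc, the level in cluster 2 was in the median 11.1 times what this share would give. This argues against free RNA as the whole source. The largest allowed shares of RNA from clusters 0, 1 and 3 would together give 28.3% of the level, which argues against doublets with those clusters as the whole source. The largest share of RNA from mesenchymal-like cluster 8 that Lum allows, 0.318%, would give 1.63% of the level. A pair of cells in a droplet would add their UMIs, and cells with at least 3 collagen UMIs had 0.889 times the UMIs of cells with none (medians 2792 in 1493 cells and 3142 in 283 cells). This ratio cannot decide on doublets, because the smaller group, richer in collagen, also had fewer UMIs (median 2399 against 2935). The ratio was not taken within the groups. At equal depth the cells with collagen held a median of 11 Krt5 and Krt14 UMIs against 20, a loss of keratin that mixed RNA would also give. Taken by group, the largest level that any allowed mixture of RNA from clusters 0, 1, 3 and 8 and free RNA would give was in the median 16.0% in the smaller and 33.3% in the larger, which argues against such mixtures as the whole source in either; epithelial-like cells may transcribe these genes themselves, a hypothesis for which no biological explanation was tested.

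In cluster 4, 28 of the 29 expressed genes from Bcat1 to Bicd1 (chromosome 6, 144993835 to 149563329) were at least 4-fold higher than in cluster 2 (96.6%), with a median of 14.9-fold, with Pthlh at 104-fold. This percent, like that of the chromosome 9 stretch below, is set in part by the 4-fold rule that drew the stretch. The 10 neighbouring genes had a median of 0.829 and the next window of the genome one of 2.10. All 10 lie before Bcat1, since no scanned gene lay beyond Bicd1, so only that border was seen. RNA from other cells is argued against by a median level 8.43 times the highest in any other cluster. A few extreme cells are argued against by 92.2% (87.0 to 95.8) of its cells lying above the 99th percentile of cluster 2. A gain of DNA copies in these cells may account for the raised stretch, as a hypothesis. No DNA was measured, and shared regulation of the stretch was not tested.

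Along 1.08 Mb of chromosome 9 (6928503 to 8004596), 9 of the 10 expressed genes, among them Yap1, Birc2, Birc3, Mmp13 and Mmp3, were at least 4-fold higher in clusters 0 to 4 together than in cluster 7 (90%), with a median of 16.2-fold against 1.27-fold in the neighbouring genes; taken alone, clusters 0 and 2 had 60% and 70% of the genes at least 4-fold higher. Free RNA is argued against by a lowest median, in cluster 2, of 6.83 times the level it could give. The test set beforehand for silence of the stretch in the lineage of cluster 7 alone, the share of UMIs in cluster 5 over cluster 2, gave 0.330, between its bounds, and did not decide; a later one, the share in the smaller over the larger epithelial-like cluster at resolution 1.0, gave 0.115 and argues against it. Macrophage-like cluster 6 held the stretch, without its Mmp genes, at a median of 0.476% of UMIs per cell, against 0.805% and 0.0926% in the larger and smaller epithelial-like clusters, 0.173% in cluster 5 and 0.186% in cluster 8, and its levels were in the median 1.22 times what the largest allowed mixture of RNA from clusters 0 to 4 and free RNA, 59.4% of its UMIs, would give; a value neither under 1 nor above 2, which leaves open whether its cells hold this RNA themselves. A gain of DNA copies in tumor cells, in which the smaller epithelial-like cluster could be cells without it, therefore stays an open hypothesis; no DNA was measured, and regulation of the stretch was not tested.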
